A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

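The data were 8 two-colour arrays of Saccharomyces cerevisiae RNA, 2 biological replicate arrays for each of 4 comparisons. Total RNA (100 ng) was amplified and labelled with Cy5 or Cy3 together with spike-in RNA, per the labels' protocols. The test RNA (glycerol, or mutant) carried Cy5 and the reference RNA (glucose, or parental) carried Cy3 on every array, per the labels, and no dye swap was made. The grouping of arrays came from the labels and the array layout.

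The scanner files held the median intensity of each spot and of its local background in both channels, as median pixel brightness made by Agilent Feature Extraction 10.10.1.1, per the file headers. The deposited files also held processed intensity values, background-subtracted, spatially detrended and scaled between dyes by that software, per the file headers. They held the log10 ratio of Cy5 over Cy3 processed signal, per the file headers. Other columns were flags of 0 or 1 for spots well above background, outliers and saturation, set by the same software per the file headers. The authors also deposited a table with 1 combined value per gene and comparison, for which the processing notes in the labels name limma without a version. The log base of the authors' table is not stated and was taken as log2 because of its slopes against the scanner ratios. Its column for the parental glycerol response had the opposite sign to the scanner's ratios (r = -0.951 across genes), while the other 3 columns had r = 0.948, 0.843 and 0.851. This table was used for values only, with the sign of that column turned.

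Ratios were computed in R 4.3.3 with limma 3.58.1. The median signals were corrected with the normexp method and an offset of 50, which pulls ratios of dim genes towards 0, and normalized by loess within each array, with control and outlier spots at weight 0. The plan named mean signals, which the files do not hold, so median signals were used. Both spots of a gene were averaged as log2 Cy5/Cy3. A gene was kept if it was well above background on every channel of at least 1 of the 4 conditions, which kept 5343 of 6256 genes, and 4718 genes passed on all 16 channels. Gene names came from the array annotation and a yeast reference, to which 5756 genes could be matched and 500 could not. Whether probes of close paralogs share signal was not analysed here. For a called gene with 1 channel not well above background on either array of a comparison, the fold is given as a lower bound. For ERG12, which was not tested, no ratio is given where a channel was that dim.

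Each gene was fitted with 1 coefficient per comparison over all 8 arrays, so that the comparisons share an estimate of the spread with 4 residual degrees of freedom, and moderated with eBayes. A gene counted as called at a Benjamini-Hochberg adjusted p under 0.05. The difference of the glycerol responses was the contrast of mutant minus parental glycerol over glucose, in which a constant dye effect of a gene cancels. Standard errors are those of the moderated fit, and SDs are between replicate arrays. The number of arrays, 2 per comparison, limits the precision. On simulated data the fit recovered 37.3% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 6 false calls among 5343 genes. With simulated gene-specific dye effects it made 123 false calls in a comparison without dye swap, against 18 in the separate-channel fit. With RNA extracts shared between arrays of a slide row it made 6, the loop model 24 and the separate-channel fit 126. In the data, the mutant glycerol response and mutant over parental in glycerol, which both hold mutant glycerol RNA, deviated together between slide rows (r = 0.763). Around the loop of 4 comparisons, the deviations between slide rows closed with 0.304 of the variance that independent arrays would give. Shared extracts are therefore possible in all 4 comparisons, and p-values of the loop and separate-channel fits may be too small. The main fit treats the 8 arrays as independent, which would then not hold.

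The 33 gene lists were written before the data were examined, as were the tests, the rule for named genes and the alternatives. They were: mevalonate pathway; late ergosterol synthesis; sterol regulators, uptake and hypoxic cell wall genes; ubiquinone and haem A synthesis; dolichol, prenylation and other isoprenoid users; respiratory chain, ATP synthase, citrate cycle, glyoxylate cycle and gluconeogenesis, glycerol metabolism and transport, glycolysis and ethanol formation, hexose transport, fatty acid oxidation and peroxisome, fatty acid and phospholipid synthesis, ribosome biogenesis, general stress and storage carbohydrate, oxidative stress defence, unfolded protein response, iron uptake regulon, drug resistance transporters, cell wall integrity, acid and weak acid response, amino acid synthesis under Gcn4, sulfate assimilation and methionine, phosphate regulon, histones and DNA replication, a-mating type and pheromone response, alpha-mating type and sporulation, strain markers, ERG12 chromosome neighbours, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, and proteasome. Lists with 5 or more measured genes, 32 of them, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 160 tests, and again with an estimated correlation and with fry. Old and new names of a gene counted once: ACR1 was read as SFC1, FEN1 as ELO2, TAF1 as ARN2, and MLP1, listed for cell wall integrity, as KDX1. A list of nitrogen catabolite genes was written after the data were seen and was not among these 160 tests.

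Named genes were ERG12, the 10 largest positive and 10 largest negative called log2 ratios per contrast with a standard name and the same sign on both arrays, up to 4 called genes per list with the largest ratios, and members of both sterol synthesis lists. For the difference of responses, both mutant arrays had to lie beyond both parental arrays. A gene of a list could be named again in other comparisons. One gene picked by this rule is not reported here.

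The alternatives were no background subtraction, the scanner's log ratios, median centring, Aquantile after loess, centring on 10 spike-in probes, no filter or a filter on all channels, eBayes with trend and robust settings, each comparison alone, a loop model, a separate-channel fit with a dye term, the slide row as a block, other estimates of the difference of responses, a 2-fold threshold, each array left out, and the authors' table. Spike-in offsets of replicates 1 and 2 were 0.97 and 0.24 in the parental response, -0.21 and 0.12 in the mutant response, 0.03 and 0.24 for the strains in glucose, and -0.88 and -0.50 for the strains in glycerol. These gaps limit what centring on the spike-in probes can show. The scripts were tested on simulated data. Control spots, outlier spots and genes under the filter were left out of the tests.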

Results

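Transcript levels were measured in budding yeast, Saccharomyces cerevisiae, on 2-colour oligonucleotide arrays. A parental strain, labelled BY4741, was set beside a mutant with a DAmP allele of ERG12, a kind of allele in which a disrupted 3' untranslated region lowers the amount of the transcript. ERG12 encodes mevalonate kinase, an enzyme of the pathway that leads to sterols, ubiquinone, haem A, dolichol and prenyl groups. Per the labels, the mutant kept 10% of the parental enzyme activity. Cells grown on glucose were moved to medium with either glucose or glycerol at 20 g/L, and the series asks how the kinase deficiency changes transcript levels on these carbon sources. The labels do not agree on what came before RNA extraction. The design text gives 1 h in the new medium. The growth protocol gives growth from an optical density of 0.1 to 0.5, the highest that the mutant reached in glycerol. The treatment protocol gives 1 h in rich medium at pH 2.5. The data do not settle which of these applied, so differences in growth phase or acid exposure stay open in every comparison.

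Each of 4 comparisons was hybridised on 2 biological replicate arrays: glycerol over glucose in the parental strain, glycerol over glucose in the mutant, mutant over parental in glucose, and mutant over parental in glycerol. The RNA named first was always labelled with Cy5 and the other with Cy3, so no comparison had a dye swap and a dye effect of a gene is part of every ratio. All 8 arrays lay on 1 slide, each comparison in a column of its own, so slide column and comparison cannot be told apart. An array carried 12512 gene spots for 6256 genes, and between 4917 and 5499 genes per channel were well above background. Median channel signals ranged from 133 to 743 scanner units, and 0 gene spots were saturated. The test covered 5343 genes, and with 2 arrays per comparison the number of arrays limits the precision. Across genes, which are not independent replicates, replicate arrays correlated at r = 0.953 for the parental glycerol response, 0.898 for that of the mutant, 0.716 for the strains in glucose and 0.511 for the strains in glycerol. Ratios added up around the loop of 4 comparisons with a median deviation of 0.02 and an SD of 0.23 on the log2 scale. In limma, 0 genes deviated from closure after adjustment, and 24 did at an unadjusted p under 0.05. That is fewer than this threshold gives by chance among 5343 genes. Between slide rows, closure had 0.304 of the variance that independent arrays would give. Deviations of RNA extracts shared around the loop would cancel in it, so closure does not show that the ratios are reliable.

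ERG12 itself (YMR208W, chromosome XIII) was dim. Its probe was well above background in 5 of 8 parental channels and in 1 of 8 mutant channels. ERG12 did not enter the filtered test because of its dim signal. In glucose the mutant channel was above background on 0 of 2 arrays, so no mutant over parental ratio is given. In glycerol each channel was above background on 1 of 2 arrays. The ratio there was -0.74 ± 0.27 (log2, SD, n = 2 arrays) in Agilent's processed values and -0.25 ± 0.09 (SE, n = 2 arrays, adjusted p = 0.206) in the fit without the filter. The glycerol over glucose ratio of ERG12 in the parental strain was 0.03 ± 0.09 (SE, n = 2 arrays, adjusted p = 0.838) in the fit without the filter. In Agilent's processed values it was 0.08 ± 0.90 (log2, SD, n = 2 arrays), with 0.72 on one array and -0.56 on the other. The glycerol channel was above background on 1 of these 2 arrays. No ratio is given for the mutant, where neither channel was above background. Where the probe lies relative to the altered 3' part of the gene was not analysed here, and ERG12 was not used to check the strain labels. URA3, the orotidine phosphate decarboxylase gene used as a genetic marker, served to check these labels for mix-ups between single arrays. It was well above background in 8 of 8 mutant channels and in 0 of the 4 channels of the parental arrays without mutant RNA. This check does not rest on how the strains came to differ in URA3.

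The parental glycerol response asks how transcript levels differed between the carbon sources in cells with normal mevalonate kinase. Several of the genes that rose most serve the use of non-fermentable carbon sources. RGI2, a respiratory growth gene, rose at least 394-fold (adjusted p = 3.76e-08), with glucose signals not well above background on either array. ADY2, an acetate transporter gene, rose by 8.35 ± 0.18 (log2, SE, n = 2 arrays, adjusted p = 4.50e-08). JEN1, the lactate and pyruvate permease gene, rose by 7.71 ± 0.17 (adjusted p = 4.50e-08) and ICL1, isocitrate lyase of the glyoxylate cycle, by 7.45 ± 0.22 (adjusted p = 1.89e-07). ACH1, SPG1, SFC1, YAT1, MPC3 and CRC1 followed with log2 ratios from 7.37 for ACH1 to 6.36 for CRC1, and SPG1 was above background in glucose on 1 of 2 arrays. Among the genes that fell, URA2, the first enzyme of pyrimidine synthesis, stood at -3.13 ± 0.14 (adjusted p = 1.50e-06). The methionine adenosyltransferase gene SAM1 stood at -2.99 ± 0.23 (adjusted p = 1.80e-05) and the low-affinity hexose transporter gene HXT3 at -2.95 ± 0.11 (adjusted p = 8.05e-07). The ribosome-associated chaperone genes SSB1 and SSB2, close copies whose probes may share signal, were at -2.92 ± 0.21 and -2.79 ± 0.24. GLY1, GCV2, MET6 and MET10 lay between -2.79 and -2.69. The sign of these ratios is glycerol over glucose, as the dyes in the labels give it. The deposited combined table of the authors has the opposite sign in this comparison, with r = -0.951 to the scanner's log ratios across genes.

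The gene lists moved in 2 directions in the parental strain. All 16 measured genes of the glyoxylate cycle and gluconeogenesis rose (16 adjusted over the list alone), with a median log2 ratio of 4.66 (camera adjusted p = 1.20e-10, and adjusted p = 0.594 with an estimated correlation). Of 27 respiratory chain genes 26 rose (26 adjusted over the list alone), among them SDH1 by 4.45 ± 0.23 and COX7 by 3.48 ± 0.22. Their median was 2.73 (adjusted p = 2.77e-11, and adjusted p = 0.594 with an estimated correlation). The 15 ATP synthase genes all rose (15 adjusted over the list alone), with STF2 at 3.29 ± 0.25 and ATP2 at 2.45 ± 0.11 (list adjusted p = 3.49e-07, and adjusted p = 0.594 with an estimated correlation). In the citrate cycle 11 of 13 rose and 1 fell (11 and 1 adjusted over the list alone). It was led by the citrate synthase genes CIT3 at 5.10 ± 0.16 and CIT1 at 3.53 ± 0.24 (list adjusted p = 0.000345, and adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation and peroxisome genes rose in 16 of 20 cases and fell in 2 (16 and 2 adjusted over the list alone). The thiolase gene POT1 rose at least 59.3-fold (list adjusted p = 3.05e-07, and adjusted p = 0.594 with an estimated correlation). General stress and storage carbohydrate genes rose in 29 of 32 cases and fell in 1 (29 and 1 adjusted over the list alone). The small heat shock protein genes HSP12 and HSP26 stood at 4.74 ± 0.18 and 4.51 ± 0.26 (list adjusted p = 9.70e-09, and adjusted p = 0.594 with an estimated correlation). Proteasome genes rose in 32 of 35 cases (32 adjusted over the list alone), with RPN10 at 1.41 ± 0.13 and RPN6 at 1.35 ± 0.16 (list adjusted p = 3.31e-07, and adjusted p = 0.594 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 37 of 61 cases and fell in 1 (37 and 1 adjusted over the list alone), with MRP20 at 1.37 ± 0.11 (list adjusted p = 1.07e-05, and adjusted p = 0.594 with an estimated correlation).

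The lists of cytosolic ribosomal proteins, ribosome biogenesis, amino acid synthesis, sulfate assimilation and methionine, and glycolysis lay lower in parental glycerol cells. Of 136 cytosolic ribosomal protein genes 134 fell (134 adjusted over the list alone), for example RPS9A at -2.60 ± 0.29. The list median was -1.46 (adjusted p = 4.71e-27, and adjusted p = 0.594 with an estimated correlation). Ribosome biogenesis genes fell in 31 of 39 cases (32 adjusted over the list alone). The RNA polymerase I subunit gene RPA190 stood at -2.57 ± 0.12 and NSR1 at -1.75 ± 0.23 (list adjusted p = 2.00e-07, and adjusted p = 0.629 with an estimated correlation). Amino acid synthesis genes under the activator Gcn4 fell in 25 of 28 cases and rose in 1 (25 and 1 adjusted over the list alone). LYS2 stood at -2.25 ± 0.16 and HIS4 at -2.16 ± 0.13 (list adjusted p = 7.10e-08, and adjusted p = 0.594 with an estimated correlation). Sulfate assimilation and methionine genes fell in 18 of 21 cases (18 lower and 1 higher adjusted over the list alone), with a median of -1.59 (adjusted p = 2.04e-07, and adjusted p = 0.594 with an estimated correlation). Glycolysis and ethanol formation genes fell in 15 of 21 cases and rose in 2 (16 and 2 adjusted over the list alone). TDH3 stood at -2.53 ± 0.23, ENO2 at -2.12 ± 0.22 and the glucokinase gene GLK1 at 2.52 ± 0.23 (list adjusted p = 0.0023, and adjusted p = 0.594 with an estimated correlation). Hexose transport genes were split, 4 higher and 4 lower of 14 (4 and 4 adjusted over the list alone), with HXT5 at 5.24 ± 0.30 and HXT1 at -2.63 ± 0.49 (list adjusted p = 0.879). Glycerol metabolism and transport genes were higher in 6 and lower in 3 of 9 cases (6 and 3 adjusted over the list alone). The glycerol phosphate dehydrogenase gene GUT2 stood at 3.29 ± 0.22 and GCY1 at 2.90 ± 0.19 (list adjusted p = 0.293).

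Of both sterol synthesis lists, late ergosterol synthesis lay lower in the parental strain and the mevalonate pathway did not pass the list test. Late ergosterol synthesis genes fell in 11 of 16 cases and rose in 2 (11 and 2 adjusted over the list alone), with a list median of -0.75 (adjusted p = 0.00739, and adjusted p = 0.594 with an estimated correlation). ERG7, lanosterol synthase, was at -1.5002 ± 0.16, ERG5 at -1.38 ± 0.12 and ERG1, squalene epoxidase, at -1.24 ± 0.10. In the mevalonate pathway 5 of 9 measured genes fell and 1 rose (5 and 1 adjusted over the list alone; list adjusted p = 0.117). The lower genes were IDI1 at -0.85 ± 0.11, ERG8 at -0.82 ± 0.10, ERG10 at -0.81 ± 0.13, HMG1, a hydroxymethylglutaryl-CoA reductase gene, at -0.75 ± 0.13 and MVD1 at -0.72 ± 0.10. The genes that rose, ERG9 at 0.41 ± 0.13, ERG29 at 0.29 ± 0.10 and the second reductase gene HMG2 at 0.54 ± 0.10, turned to -0.58, -0.60 and -0.45 when arrays were centred on spike-in probes.

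In all, limma called 3310 of 5343 genes in the parental strain at an adjusted p under 0.05, 1679 higher and 1631 lower, of which 685 and 496 changed at least 2-fold. These directions are relative to the average gene of an array. Centring on the spike-in probes moved the median of all genes to -0.74 and left 10.4% of 3202 calls higher, against 50.7% here. The spike-in offset was 0.97 on one parental array and 0.24 on the other, so the size of this shift is uncertain.

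The mutant glycerol response asks whether the same shift took place with low mevalonate kinase. Many of the leading genes were those of the parental strain. ICL1 rose by 7.51 ± 0.22 (log2, SE, n = 2 arrays, adjusted p = 2.55e-07) and JEN1 by 6.58 ± 0.17 (adjusted p = 1.98e-07). RGI2 rose at least 118-fold, ADY2 at least 108-fold and the malate synthase gene MLS1 at least 62.9-fold, all with glucose signals not well above background on either array. ACH1, CRC1, GRE1, SPS100 and SFC1 lay between 5.86 for ACH1 and 5.52 for SFC1. The genes that fell most were led by hexose transporters: HXT2 at -3.98 ± 0.39 (adjusted p = 0.000126), and HXT1 at -3.68 ± 0.49 (adjusted p = 0.000624). HXT3 stood at -3.33 ± 0.11 (adjusted p = 5.11e-07) and HXT4 at -2.55 ± 0.27 (adjusted p = 0.000184). The phosphate transporter gene PHO84 was at -3.06 ± 0.30 (adjusted p = 0.000125), AQR1 at -2.51 ± 0.11, GPP2 at -2.16 ± 0.24 and NSR1 at -1.96 ± 0.23. MIG2 and MIG3, genes of glucose repressors, were at -2.42 ± 0.19 and -2.08 ± 0.26.

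All 16 glyoxylate cycle and gluconeogenesis genes rose in the mutant as well (16 adjusted over the list alone), with a median of 4.12 (adjusted p = 2.53e-13, and adjusted p = 0.594 with an estimated correlation). Respiratory chain genes rose in 26 of 27 cases (26 adjusted over the list alone), with SDH1 at 3.47 ± 0.23 and COX7 at 2.91 ± 0.22 (list adjusted p = 9.63e-12, and adjusted p = 0.594 with an estimated correlation). ATP synthase genes rose in 14 of 15 cases (15 adjusted over the list alone), STF2 by 2.43 ± 0.25 and ATP2 by 2.10 ± 0.11 (list adjusted p = 3.25e-07, and adjusted p = 0.594 with an estimated correlation). The citrate cycle had 11 of 13 higher and 1 lower (11 and 1 adjusted over the list alone), with CIT3 at 4.57 ± 0.16 (list adjusted p = 1.22e-05, and adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation and peroxisome genes had 16 of 20 higher and 1 lower (16 and 1 adjusted over the list alone), with POT1 at least 22.3-fold higher. Their list had adjusted p = 1.87e-09, and adjusted p = 0.594 with an estimated correlation. General stress and storage carbohydrate genes rose in 27 of 32 cases (28 adjusted over the list alone), HSP26 by 4.13 ± 0.26 and HSP12 by 4.05 ± 0.18 (list adjusted p = 1.20e-10, and adjusted p = 0.594 with an estimated correlation). Proteasome genes rose in 15 of 35 cases (9 adjusted over the list alone; list adjusted p = 0.00185, and adjusted p = 0.741 with an estimated correlation). Mitochondrial ribosomal protein genes rose in 17 of 61, with 2 lower (15 and 1 adjusted over the list alone; list adjusted p = 0.23).

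Cytosolic ribosomal protein genes fell in 130 of 136 cases in mutant glycerol cells (134 adjusted over the list alone). The median was -1.23, and RPS9A stood at -1.96 ± 0.29 (list adjusted p = 1.27e-33, and adjusted p = 0.594 with an estimated correlation). Ribosome biogenesis genes fell in 32 of 39 cases (34 adjusted over the list alone), RPA190 standing at -1.88 ± 0.12 (list adjusted p = 6.11e-11, and adjusted p = 0.594 with an estimated correlation). Amino acid synthesis genes fell in 19 of 28 cases and rose in 1 (20 and 1 adjusted over the list alone; list adjusted p = 4.34e-06, and adjusted p = 0.594 with an estimated correlation). Sulfate assimilation and methionine genes fell in 15 of 21 and rose in 2 (15 and 3 adjusted over the list alone; list adjusted p = 0.000128, and adjusted p = 0.594 with an estimated correlation). Glycolysis and ethanol formation genes fell in 9 of 21 cases and rose in 3 (10 and 3 adjusted over the list alone), with a median of -0.47 (list adjusted p = 0.0172, and adjusted p = 0.594 with an estimated correlation). Hexose transport genes were lower in 5 and higher in 4 of 14 cases (6 and 4 adjusted over the list alone; list adjusted p = 0.206). Glycerol metabolism and transport genes were higher in 5 and lower in 2 of 9 (5 and 2 adjusted over the list alone; list adjusted p = 0.269). GCY1 stood at 2.93 ± 0.19 and GUT2 at 2.61 ± 0.22.

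Late ergosterol synthesis genes fell in 9 of 16 cases in the mutant and rose in 1 (9 and 1 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.0213, and adjusted p = 0.594 with an estimated correlation). ERG1 stood at -1.03 ± 0.10, ERG2 at -0.96 ± 0.16, ERG7 at -0.93 ± 0.16 and ERG24 at 0.41 ± 0.13. In the mevalonate pathway 2 of 9 genes fell, ERG8 at -0.66 ± 0.10 and IDI1 at -0.64 ± 0.11, and HMG2 rose by 0.44 ± 0.10 (2 and 1 adjusted over the list alone; list adjusted p = 0.654).

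Across the mutant response, limma called 2491 genes, 1319 higher and 1172 lower, of which 447 and 288 changed at least 2-fold. Without mutant replicate 2 the count was 1453, and with spike-in centring it was 1139, where ERG2, ERG7, ERG8, IDI1, ERG24 and HMG2 no longer passed. Both responses called 1154 genes higher and 1045 lower, where independent lists of these sizes would share 414 and 358. In opposite directions, 0 genes were higher in the parental strain and lower in the mutant. The reverse held for 4 genes, SPC110, MET30, ACS2 and UBP2, named after their values were seen.

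The mutant over parental comparison in glucose asks how the strains differed on the preferred carbon source. URA3 was higher in the mutant by 5.55 ± 0.13 (log2, SE, n = 2 arrays, adjusted p = 3.49e-07), a gene used as a strain marker. In both strain comparisons its parental signal beside mutant RNA was 26.0 to 99.1, against at most 14.2 on the parental arrays without mutant RNA, so its ratios do not give the full size of the difference. Effects of the URA3 difference and of the ERG12 allele cannot be told apart in any contrast of the strains. The phosphate transporter genes PHO84 and PHO89 were higher by 2.10 ± 0.30 (adjusted p = 0.00852) and 1.58 ± 0.23 (adjusted p = 0.0087). CHS2, chitin synthase of the division septum, was higher by 1.88 ± 0.12 (adjusted p = 0.000485) and the mitotic cyclin gene CLB1 by 1.44 ± 0.10 (adjusted p = 0.000637). The cell wall genes YGP1, NCA3 and PIR3 were at 1.78 ± 0.22, 1.74 ± 0.21 and 1.44 ± 0.34, and HSP26 and TDH1 at 1.70 ± 0.26 and 1.59 ± 0.14. All 10 genes with the largest lower ratios act in the use of poor nitrogen sources. DAL5 stood at -2.20 ± 0.21 (adjusted p = 0.00218), and DAL4 at -2.20 ± 0.20 (adjusted p = 0.00218). Next came the repressor gene DAL80 at -1.95 ± 0.18 (adjusted p = 0.00218) and the urea permease gene DUR3 at -1.87 ± 0.13 (adjusted p = 0.00063). DAL1, GAP1, DAL3, DAL7, DAL2 and MEP2, genes of allantoin breakdown and of amino acid and ammonium uptake, lay between -1.78 and -1.46.

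Few sterol genes differed between the strains in glucose. In late ergosterol synthesis 2 of 16 genes were lower (6 adjusted over the list alone), ERG27 at -0.51 ± 0.12 (adjusted p = 0.0441) and ERG6 at -0.44 ± 0.10 (adjusted p = 0.0404). The list had a median of -0.33 (adjusted p = 0.00116, and adjusted p = 0.594 with an estimated correlation). HMG1 was the mevalonate pathway gene that passed, at -0.64 ± 0.13 (adjusted p = 0.0272), 1 of 9 (2 adjusted over the list alone; list adjusted p = 0.391). HMG1, ERG27 and ERG6 no longer passed with median centring, with spike-in centring or without either array of this comparison. PDR11, a sterol uptake transporter gene, was lower at -0.99 ± 0.13 (adjusted p = 0.00782), 1 of 2 lower genes among 20 sterol regulator, uptake and hypoxic cell wall genes (3 adjusted over the list alone; list adjusted p = 0.269).

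Other lists shifted by little in glucose. Sulfate assimilation and methionine genes were higher in 6 of 21 cases (6 adjusted over the list alone), SUL1 by 1.17 ± 0.13 and MUP1 by 1.15 ± 0.15 (list adjusted p = 0.00287, and adjusted p = 0.609 with an estimated correlation). Acid and weak acid response genes were higher in 2 of 14 cases, YGP1 and YRO2 (2 adjusted over the list alone; list adjusted p = 0.0128, and adjusted p = 0.594 with an estimated correlation). Hexose transport genes were higher in 3 of 14 cases, among them HXT4 at 1.35 ± 0.27 and HXT5 at 1.33 ± 0.30 (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0282, and adjusted p = 0.597 with an estimated correlation). Proteasome genes had a median of 0.25 with 0 of 35 past the test (0 adjusted over the list alone; list adjusted p = 0.000197, and adjusted p = 0.682 with an estimated correlation). Ribosome biogenesis genes were higher in 3 of 39 cases (4 adjusted over the list alone; list adjusted p = 0.00341, and adjusted p = 0.779 with an estimated correlation). General stress and storage carbohydrate genes were higher in 4 of 32 cases (6 adjusted over the list alone; list adjusted p = 0.0126, and adjusted p = 0.741 with an estimated correlation). Cell wall integrity genes went both ways, 4 higher and 2 lower of 16 (6 and 4 adjusted over the list alone), with CIS3 at 1.14 ± 0.23 and CWP1 at -1.23 ± 0.15 (list adjusted p = 0.453). Histone and DNA replication genes were lower in 3 of 15 cases (3 lower and 1 higher adjusted over the list alone), HTA2 at -1.05 ± 0.17 and HTB2 at -0.74 ± 0.10 (list adjusted p = 0.0862).

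In glucose limma called 376 genes, 187 higher and 189 lower in the mutant, and 1453 genes had an unadjusted p under 0.05. The count was 12 without replicate 1 of this comparison and 5 without replicate 2, namely URA3, CHS2, CLB1, DUR3 and YNL058C, the last chosen after its values were seen. It was 111 with median centring, 59 with spike-in centring, 729 with this comparison fitted alone, 968 in the loop model and 746 in the separate-channel fit.

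The mutant over parental comparison in glycerol asks the same on the carbon source that limits mutant growth. URA3 was again higher, by 5.29 ± 0.13 (log2, SE, n = 2 arrays, adjusted p = 5.11e-07), with the parental channel above background on 1 of 2 arrays. GRE1, a gene of desiccation and acid stress, was higher by 2.34 ± 0.13 (adjusted p = 0.000197) and the phosphogluconate dehydrogenase gene GND2 by 2.10 ± 0.18 (adjusted p = 0.00123). CHS2, YGP1 and PHO89 were higher as in glucose, at 1.90 ± 0.12, 1.88 ± 0.22 and 1.77 ± 0.23. The sulfate permease gene SUL2 was higher by 1.88 ± 0.15 (adjusted p = 0.000803), and SPS100 and the cell wall genes CIS3 and PIR3 by 1.76 ± 0.29, 1.71 ± 0.23 and 1.66 ± 0.34. PDC5, a pyruvate decarboxylase gene, had the largest lower ratio, -1.76 ± 0.32 (adjusted p = 0.0229). DAL80 stood at -1.40 ± 0.18, and DAL3, DAL7, DAL5, DAL1, DUR3 and MEP2 lay between -1.24 for DAL3 and -0.998 for MEP2. EEB1 was at -1.37 ± 0.23 and the daughter cell separation gene DSE4 at -1.01 ± 0.13.

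Sulfate assimilation and methionine was the list with the largest share of called genes in glycerol: 17 of 21 genes were higher in the mutant (20 adjusted over the list alone), with a median of 1.18 (adjusted p = 4.59e-22, and adjusted p = 0.594 with an estimated correlation). MET5 stood at 1.64 ± 0.14, MET3 at 1.64 ± 0.10 and MET6 at 1.54 ± 0.19. Cell wall integrity genes were higher in 6 of 16 cases and lower in 1 (9 and 1 adjusted over the list alone), PIR1 by 1.53 ± 0.16 and YPS3 by 1.16 ± 0.23 (list adjusted p = 0.00223, and adjusted p = 0.594 with an estimated correlation). Acid and weak acid response genes were higher in 5 of 14 cases (7 adjusted over the list alone; list adjusted p = 0.000345, and adjusted p = 0.594 with an estimated correlation). Amino acid synthesis genes were higher in 4 of 28 cases (8 adjusted over the list alone), LYS2 by 1.15 ± 0.16 and SNZ1 by 1.13 ± 0.14 (list adjusted p = 0.000393, and adjusted p = 0.66 with an estimated correlation). Glycolysis and ethanol formation genes were higher in 4 of 21 cases and lower in 1 (5 and 1 adjusted over the list alone), with TDH3 at 1.16 ± 0.23 (list adjusted p = 0.000156, and adjusted p = 0.594 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 5 of 136 cases (20 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.05e-14, and adjusted p = 0.594 with an estimated correlation). Ribosome biogenesis genes had a median of 0.15 with 0 of 39 called (0 adjusted over the list alone, list adjusted p = 0.0423, and adjusted p = 0.857 with an estimated correlation). Relative to all genes, this list turned to -0.0064 without replicate 1 of this comparison. Strain markers were higher in 3 of 5 cases, URA3, MET17 and LYS2 (4 adjusted over the list alone; list adjusted p = 0.000122, and adjusted p = 0.594 with an estimated correlation).

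Mitochondrial and proteolytic lists lay lower in mutant glycerol cells, with few single genes past the test. Respiratory chain genes had a median of -0.27 and ATP synthase genes of -0.33, with 0 of 27 and 0 of 15 called (0 in each adjusted over the list alone; list adjusted p = 0.000156 and 0.000652, and adjusted p = 0.629 and 0.597 with an estimated correlation). Mitochondrial ribosomal protein genes were lower in 3 of 61 cases (3 adjusted over the list alone), with MRP20 at -0.66 ± 0.11 (list adjusted p = 2.16e-10, and adjusted p = 0.594 with an estimated correlation). Proteasome genes were lower in 1 of 35 cases, RPN9 at -0.58 ± 0.12 (3 adjusted over the list alone; list adjusted p = 1.85e-07, and adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation and peroxisome genes had a median of -0.19 with 0 of 20 called (1 lower adjusted over the list alone; list adjusted p = 0.00153, and adjusted p = 0.594 with an estimated correlation). ADY2 at -0.84 ± 0.18 and JEN1 at -0.75 ± 0.17 were lower, 2 of 16 glyoxylate cycle and gluconeogenesis genes (3 higher and 2 lower adjusted over the list alone; list adjusted p = 0.868). With spike-in centring MRP20, RPN9 and PDR11, the last at -0.73 ± 0.13 here, turned to 0.13, 0.20 and 0.05.

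In glycerol 0 of 9 mevalonate pathway genes and 0 of 16 late ergosterol synthesis genes passed (0 in each adjusted over the list alone; list adjusted p = 0.303 and 0.45). HMG1 stood at 0.23 ± 0.13 (adjusted p = 0.364), ERG27 at -0.19 ± 0.12 (adjusted p = 0.43) and ERG6 at -0.15 ± 0.10 (adjusted p = 0.467).

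In glycerol limma called 220 genes, 173 higher and 47 lower in the mutant, and 1081 had an unadjusted p under 0.05. The count was 18 without replicate 1 of this comparison, 108 without replicate 2, and 141 without either array of the glucose comparison, which gives part of the pooled spread. It was 120 with median centring, 88 with this comparison fitted alone, 732 in the loop model, 1029 in the separate-channel fit (428 higher and 601 lower, the opposite balance) and 3227 with spike-in centring, which moved the median of all genes to 0.73. Both strain comparisons called 68 genes higher, against 6.05 for independent lists (Fisher's exact test, one-sided, p = 1.62e-57), and 18 lower, against 1.66 (exact p = 6.25e-15). These comparisons share no array, but they share the dye orientation, so part of the excess may come from gene-specific dye effects. In the separate-channel fit, which has a dye term, 98 genes were shared higher against 18.4, and 129 lower against 58.0. That fit uses all arrays for both comparisons, and its p-values may be too small. Fisher's test treats genes as independent, and both lists use the same pooled spread of each gene.

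**Figure D1:**
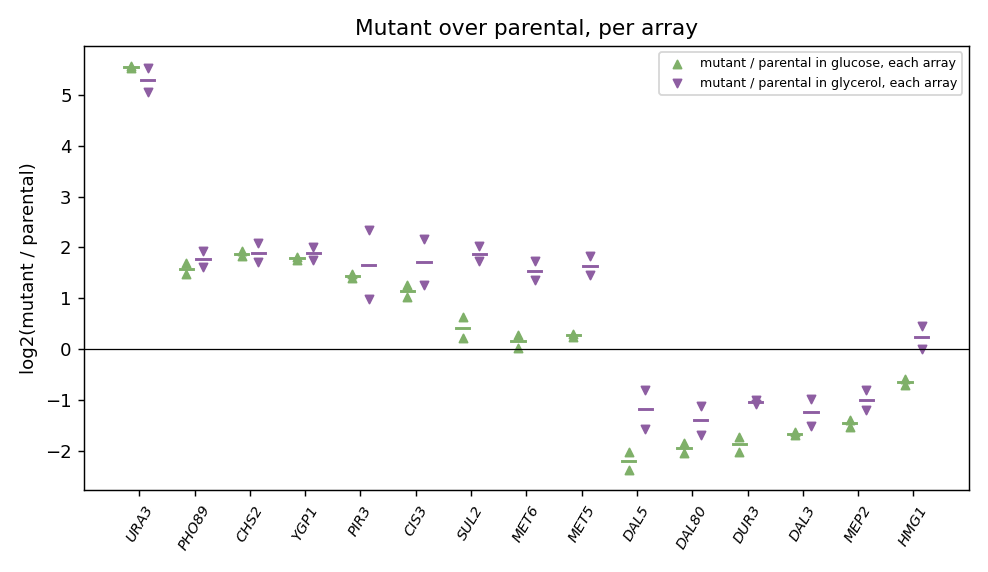
Log2 ratio of mutant over parental for 15 genes, with each triangle an array, upright for glucose and inverted for glycerol, and each short bar the mean of 2 arrays. URA3 lay at 5.55 in glucose and 5.29 in glycerol, SUL2, MET6 and MET5 were higher in glycerol, and DAL5 and DAL80 lay below 0 on all 4 arrays.

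The difference of both glycerol responses, mutant minus parental, tests whether the strains responded differently to glycerol. A positive value means a larger log2 ratio in the mutant, which for a gene that fell is a smaller decrease. The largest positive difference was that of TDH3, a glyceraldehyde phosphate dehydrogenase gene, at 2.06 ± 0.33 (log2, SE, n = 4 arrays, adjusted p = 0.034). Next came MET6 at 2.03 ± 0.26 (adjusted p = 0.0243) and URA2 at 1.95 ± 0.20 (adjusted p = 0.0178). Besides MET6, genes of methionine synthesis and sulfate assimilation with large positive differences were MET13 at 1.77 ± 0.34, SUL2 at 1.58 ± 0.21, MET17 at 1.54 ± 0.29, MET10 at 1.48 ± 0.20 and MET5 at 1.39 ± 0.20. MET6 fell to -2.71 in the parental strain and to -0.68 in the mutant. GND2 differed by 1.45 ± 0.25 and ADH5 by 1.38 ± 0.14. On the negative side CMK1, a calmodulin-dependent kinase gene, differed by -1.75 ± 0.30 (adjusted p = 0.0412), and the sphingolipid synthesis gene SUR1 by -1.75 ± 0.23 (adjusted p = 0.0243). HEF3 differed by -1.504 ± 0.26, ACH1 by -1.502 ± 0.25 and the mitochondrial elongation factor gene MEF2 by -1.43 ± 0.20. Negative values were also fitted for RGI2 at -1.90 ± 0.25, POT1 at -1.69 ± 0.17, ADY2 at -1.59 ± 0.26, ALT2 at -1.53 ± 0.18 and ACS1 at -1.51 ± 0.21. For these the mutant glucose channel was not well above background on either array, so the mutant response is a lower bound and a smaller response is not shown. For RGI2 and POT1 the parental glucose channel was not well above background either.

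**Figure D2:**
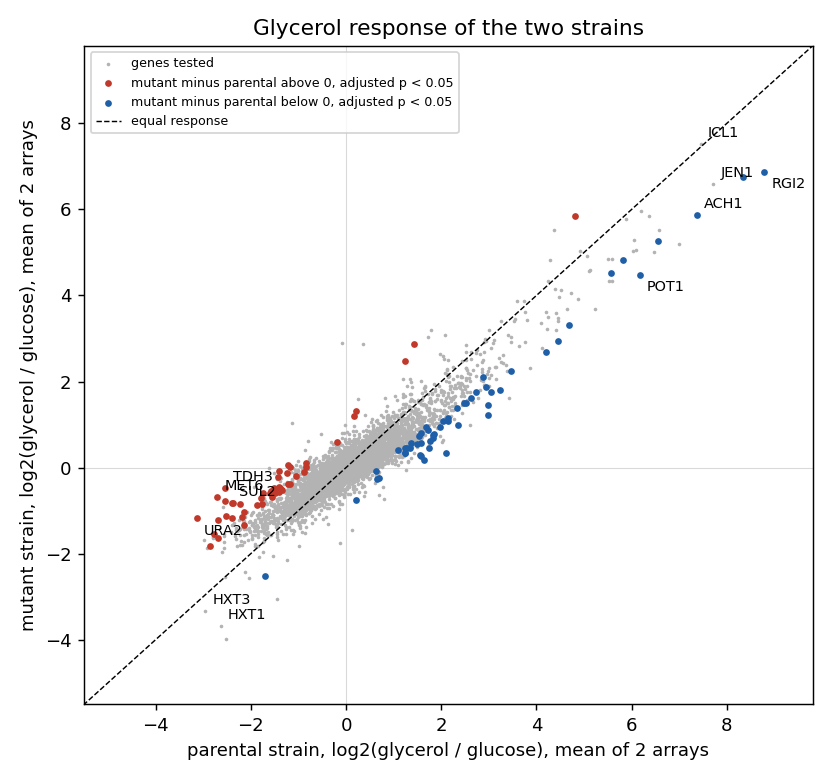
Glycerol over glucose log2 ratio of each of 5343 genes, parental strain on the horizontal axis and mutant on the vertical axis, each a mean of 2 arrays. Red and blue points are the 46 genes with a larger and the 54 with a smaller log2 ratio in the mutant at an adjusted p under 0.05. Most of them lie between the dashed line of equal response and the horizontal axis.

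By list, sulfate assimilation and methionine had 10 of 21 genes with a larger log2 ratio in the mutant (15 adjusted over the list alone) and a median difference of 1.02 (adjusted p = 9.67e-12, and adjusted p = 0.594 with an estimated correlation). Amino acid synthesis had 1 of 28 (11 adjusted over the list alone) and a median of 0.50 (adjusted p = 1.66e-07, and adjusted p = 0.594 with an estimated correlation). Glycolysis and ethanol formation had a median of 0.43 with 1 of 21 genes called (6 adjusted over the list alone; list adjusted p = 0.00223, and adjusted p = 0.594 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.24 with 1 of 136 called (0 adjusted over the list alone; list adjusted p = 3.38e-06, and adjusted p = 0.682 with an estimated correlation). Proteasome genes had a median of -0.57 with RPN4 called, 1 of 35 (16 adjusted over the list alone; list adjusted p = 2.27e-09, and adjusted p = 0.594 with an estimated correlation). Respiratory chain genes had a median of -0.59 with QCR2 called, 1 of 27 (10 adjusted over the list alone; list adjusted p = 1.85e-07, and adjusted p = 0.594 with an estimated correlation). ATP synthase genes had a median of -0.53 with 0 of 15 called (6 adjusted over the list alone; list adjusted p = 9.71e-05, and adjusted p = 0.594 with an estimated correlation). Mitochondrial ribosomal protein genes had a median of -0.37 with 2 of 61 called (9 adjusted over the list alone; list adjusted p = 2.46e-10, and adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation and peroxisome genes had 3 of 20 with a negative and 1 with a positive difference (8 and 1 adjusted over the list alone; list adjusted p = 0.00282, and adjusted p = 0.594 with an estimated correlation). POT1 is among the negative ones, and a smaller response of it is not shown. Glyoxylate cycle and gluconeogenesis genes had 2 of 16 with a negative difference (6 negative and 1 positive adjusted over the list alone; list adjusted p = 0.0213, and adjusted p = 0.629 with an estimated correlation). These are ADY2 and ACS1, for which a smaller response is not shown. Hexose transport genes had a median of -0.85 with 0 of 14 called (2 negative adjusted over the list alone; list adjusted p = 0.00205, and adjusted p = 0.594 with an estimated correlation). The citrate cycle gene MDH1 differed by -1.21 ± 0.16 (adjusted p = 0.0243), 1 of 13 (1 adjusted over the list alone; list adjusted p = 0.756). QCR2 at -0.98 ± 0.17, RPN4 at -0.89 ± 0.17 and MRP20 at -0.81 ± 0.15 turned to 0.20, 0.21 and 0.30 with spike-in centring.

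The mevalonate pathway differed between the strains by a median of 0.21 and late ergosterol synthesis by 0.30, with 0 of 9 and 0 of 16 genes called (3 and 0 adjusted over the list alone; list adjusted p = 0.0212 and 0.0203, and adjusted p = 0.594 with an estimated correlation for both). ERG10 stood at 0.83 ± 0.19 (adjusted p = 0.0641), HMG1 at 0.75 ± 0.18 (adjusted p = 0.0724) and MVD1 at 0.55 ± 0.14 (adjusted p = 0.0835). Cell wall integrity genes differed by a median of 0.30 with 1 of 16 called, CHS3 at 1.14 ± 0.20 (3 adjusted over the list alone; list adjusted p = 0.0174, and adjusted p = 0.629 with an estimated correlation).

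**Figure D3:**
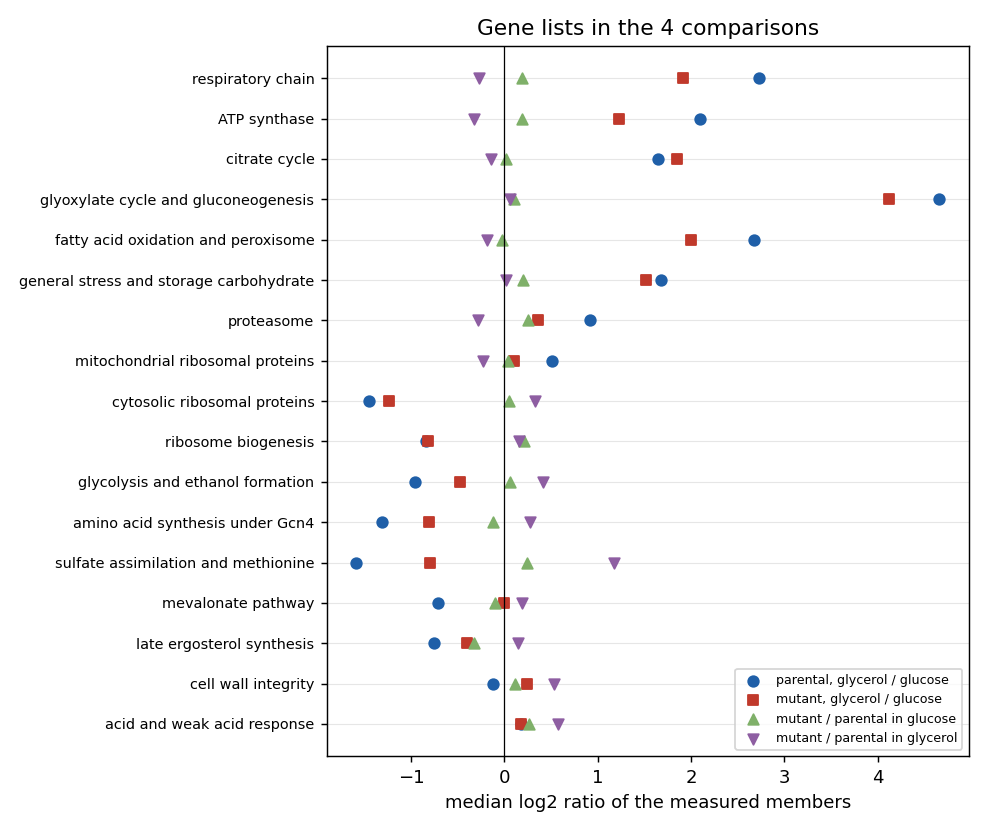
Median log2 ratio of the measured members of 17 gene lists in each of the 4 comparisons, each symbol a comparison. The parental and mutant glycerol responses share their direction in most lists, and sulfate assimilation and methionine stands at -1.59 in the parental response and at 1.18 in mutant over parental in glycerol.

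Of 5343 genes limma called 100 with a different glycerol response, 46 larger and 54 smaller in log2 ratio, and 1135 had an unadjusted p under 0.05. Larger and smaller calls were 240 and 18 with median centring, and 2428 and 0 with spike-in centring, which moved the median of all genes to 0.94. The count was 0 without parental response replicate 1, parental response replicate 2, mutant response replicate 1, or either replicate of mutant over parental in glucose (1050, 824, 589, 1000 and 1000 genes at an unadjusted p under 0.05), and 223 without mutant response replicate 2. Formed from the strain comparisons in place of the responses, the difference was called for 1 gene, GRE1, at 2.12 (adjusted p = 0.0134), and formed as the mean of both for 773. It was called for 20 genes with Agilent's log ratios, 164 without background subtraction, 258 with median centring and 2428 with spike-in centring. Changes of the model gave 26 with a trended robust prior, 11 with each comparison alone, 43 with the slide row as a block, 1030 in the loop model and 1256 in the separate-channel fit. Across genes both responses correlated at r = 0.925, and the mutant response rose by 0.762 per unit of the parental response.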

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

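The tests of explanations for the smaller mutant response and for the URA3 signal were chosen only after the result was seen, while the limma contrast and the list tests were planned. The difference between the glycerol responses of the strains, tested as a contrast in limma, singled out 46 genes with a larger and 54 with a smaller log2 ratio in the mutant. Larger ratios were found for TDH3 (2.06), MET6 (2.03), URA2 (1.95), MET13 (1.77), SUL2 (1.58), MET17 (1.54), MET10 (1.48), GND2 (1.45), MET5 (1.39) and ADH5 (1.38). Smaller ratios were found for RGI2 (-1.90), CMK1 (-1.75), SUR1 (-1.75), POT1 (-1.69), ADY2 (-1.59), ALT2 (-1.53), ACS1 (-1.51), HEF3 (-1.504), ACH1 (-1.502) and MEF2 (-1.43). For RGI2, POT1, ADY2, ALT2 and ACS1 the mutant glucose channel was not well above background on either array, so a smaller response of these genes is not shown. By list, the median difference was 1.02 for sulfate assimilation and methionine, 0.50 for amino acid synthesis under Gcn4, and 0.43 for glycolysis and ethanol formation. It was 0.30 for cell wall integrity, 0.30 for late ergosterol synthesis, 0.24 for cytosolic ribosomal proteins and 0.21 for the mevalonate pathway. It was -0.85 for hexose transport, -0.59 for the respiratory chain, -0.57 for the proteasome, -0.53 for ATP synthase, -0.37 for mitochondrial ribosomal proteins, -0.27 for fatty acid oxidation and peroxisome and -0.20 for the glyoxylate cycle and gluconeogenesis. With an estimated inter-gene correlation, 0 of 32 lists passed.

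Across genes, the mutant response was smaller than the parental response, with a slope of 0.762. The spike-in probes showed no ratio compression on the mutant arrays, where their slope was 1.03 times that on the parental arrays. They do not test compression of genes near background. Of the 10 genes named with a smaller ratio, 5 had a mutant glucose channel not above background on either array. For the slope, the normalizations tried were excluded, since it was at most 0.761 under the others that can move it. It was 0.686 with mutant array 1 alone and 0.837 with mutant array 2 alone. For the count of genes with a smaller log2 ratio, normalization was not excluded. That count was 54 here, 84 without background subtraction, 18 with median centring and 5 with Agilent's log ratios. The last also differ in background treatment. A smaller log2 ratio is a smaller response only for genes that rose, so this count covers part of the pattern. A smaller response of mutant cells fits the mutant over parental arrays, which were not used for the responses: their difference between glycerol and glucose had a mean slope of -0.18 on the parental response, -0.25 and -0.10 in the 2 pairings of slide rows. This test is weaker if arrays share RNA extracts. It does not separate an effect of mevalonate kinase from the growth limit of mutant cells in glycerol or from the strain difference in URA3.

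URA3 stood out by its signal in all mutant channels. A dye effect was excluded, since mutant channels exceeded parental channels of the same dye by at least 5.42 on the log2 scale. A mix-up of strains between single arrays was excluded, with 0 channels against their labels among the 8 mutant channels and the 4 channels of the parental arrays. A swap of the strain names on all arrays would give the same count, so it was not excluded. URA3 does not check the carbon source labels. URA3 was above background in 3 parental channels beside mutant RNA, at no more than 0.875% of the mutant signal. A URA3 marker carried by the mutant strain only stays open, because URA3 above background in 0 of 4 channels of the parental arrays is the observation itself, and the marker was not analysed here.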

How the results depend on the processing

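All alternatives here were planned, and where a result moved, the cause was not tested. Called genes picked for naming were followed through every alternative that tested them, without the 2-fold threshold and the authors' table, which gave no call. The call held throughout for 63 of 75 in the parental response, and 45 of 53 in the mutant response. It held for 4 of 42 for the strains in glucose (URA3, CHS2, CLB1 and DUR3), 8 of 38 for the strains in glycerol (URA3, GRE1, GND2, CHS2, SUL2, MET5, MET3 and GSH1) and 0 of 30 for the difference of responses. Over all settings, 4540 values of named genes kept direction and call, 578 lost the call, 20 gained it, 104 untested values moved and 11 reversed. For gene lists 3314 kept theirs, 157 lost it, 102 gained it and 1 reversed, and of the counts 67 stayed within 1.5 times and 40 moved. These totals overstate stability. They include Aquantile, which could change nothing and added 248 named gene values, 160 lists and 5 counts as unchanged. They also include fits without an array of another comparison. Signals near background limit the genes tested, and for ERG12 no firm ratio could be given.

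Counts of called genes are given in the order parental response (3310), mutant response (2491), strains in glucose (376), strains in glycerol (220) and difference of responses (100), where they moved. With a 2-fold threshold they were 1181, 735, 55, 72 and 60. With spike-in centring the last 4 were 1139, 59, 3227 and 2428, and with median centring the last 3 were 111, 120 and 258. Each comparison alone gave 729, 88 and 11, the loop model 968, 732 and 1030, and the separate-channel fit 746, 1029 and 1256. The difference of responses was called for 164 genes without background subtraction, 20 with Agilent's processed log ratio, 26 with trend and robust settings, 1 from the mutant over parental comparisons and 773 from the mean of both estimates. With the slide row, which holds the replicate number, as a block, it was called for 43, and the other 4 counts stayed within 1.5 times. Leaving out each array gave 2246 to 3281, 1453 to 2497, 5 to 368, 18 to 281 and 0 to 223 genes, where a lone array was assumed to vary like the other comparisons.

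The share of higher calls was 50.7%, 53.0%, 49.7%, 78.6% and 46% in the same order, against 10.4%, 67.6%, 33.9%, 99.9% and 100% with spike-in centring. With median centring the parental share was 37.8% and that of the difference 93.0%. The latter was 75% with Agilent's processed log ratio and 69.2% with trend and robust settings. With separate channels the share was 30.8% for the strains in glucose and 41.6% for the strains in glycerol, where the loop model gave 60.2%. Spike-in centring moved the median of all genes to -0.74, 0.07, -0.14, 0.73 and 0.94, and it reversed ERG9 (-0.58), ERG29 (-0.60) and HMG2 (-0.45) in the parental response. It also reversed PDR11 (0.051), MRP20 (0.13), RPN9 (0.20) and GAP1 (0.076) for the strains in glycerol, and QCR2 (0.20), AQR1 (0.094), RPN4 (0.21) and MRP20 (0.30) in the difference. The ribosome biogenesis list for the strains in glycerol, relative to all genes, ranged from -0.0064 without replicate 1 of that comparison to 0.30 without replicate 2. The lists called by fry were 22, 20, 2, 6 and 3. The brightest probe per gene was not run, since each gene had 1 probe, and Aquantile leaves ratios unchanged.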

Other observations

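The list of nitrogen catabolite genes and the tests on MET17 and mating type were chosen only after the result was seen, while the other list tests were planned. Nitrogen catabolite genes, which serve the uptake and breakdown of poor nitrogen sources, were lower in the mutant in glucose. Of 35 measured, 16 were lower and 30 had negative ratios, with a median of -0.55 (camera adjusted p = 1.31e-13, and adjusted p = 0.00986 with an estimated correlation). UGA4 and PUT4, permease genes for aminobutyrate and proline, stood at -1.22 ± 0.12 and -1.22 ± 0.15 (log2, SE, n = 2 arrays), CAN1 at -0.93 ± 0.16 and the activator gene GAT1 at -0.91 ± 0.16. In glycerol 8 were lower, with a median of -0.20 (adjusted p = 6.90e-06, and adjusted p = 0.0203 with an estimated correlation). There GAP1 was at -0.70 ± 0.15 and DAL4 at -0.83 ± 0.20 (adjusted p = 0.0603). With spike-in centring GAP1 turned to 0.076 in glycerol. This list was not among the 160 planned list tests, so its adjusted p-values cannot be set beside those of the planned lists. It was drawn up because such genes led the lower genes, so the 25 members not named before are the fairer set. Of these, 6 were lower in glucose (adjusted p = 2.92e-05, and adjusted p = 0.0980 with an estimated correlation) and 0 in glycerol (adjusted p = 0.232).

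Single stress and transport genes changed with the carbon source, while their lists did not pass in the parental response. Oxidative stress defence genes rose in 14 of 22 cases and fell in 6 in each response (14 and 6 adjusted over the list alone in each; list adjusted p = 0.0949 in the parental strain and 0.0574 in the mutant). SOD2 stood at 3.87 ± 0.22 and AHP1 at 3.25 ± 0.16 in the parental strain, and SOD1 at 2.49 ± 0.17 and AHP1 at 2.44 ± 0.16 in the mutant. In glucose 3 of them were higher and 1 lower in the mutant (4 and 1 adjusted over the list alone; list adjusted p = 0.0413, and adjusted p = 0.594 with an estimated correlation). In glycerol 3 were higher (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.708). GSH1, of glutathione synthesis, was at 0.67 ± 0.10 in glucose and 1.09 ± 0.10 in glycerol. Drug resistance transporter genes were higher in 4 and lower in 9 of 16 cases in the parental response (4 and 9 adjusted over the list alone; list adjusted p = 0.112). PDR10 stood at 1.99 ± 0.15 and PDR5 at -1.92 ± 0.24, and AQR1 was higher in the mutant in glucose by 0.77 ± 0.11. Iron uptake genes rose in 3 and fell in 2 of 18 cases (3 and 2 adjusted over the list alone; list adjusted p = 0.988), with FIT2 at 3.76 ± 0.41 and HMX1 at 2.42 ± 0.11. Phosphate genes fell in 6 of 12 cases and rose in 1 (6 and 1 adjusted over the list alone; list adjusted p = 0.303), with PHO84 at -1.44 ± 0.30. In mutant glycerol cells PHO11 was among 3 higher genes at 0.69 ± 0.12 (4 higher and 1 lower adjusted over the list alone; list adjusted p = 0.117). Cell wall integrity genes were split in the parental response, 3 higher and 4 lower of 16 (3 and 4 adjusted over the list alone; list adjusted p = 0.543), with FKS1 at -1.81 ± 0.11. Acid and weak acid response genes were split too, 4 higher and 4 lower of 14 (5 and 4 adjusted over the list alone; list adjusted p = 0.607), with GRE1 at 4.81 ± 0.13.

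Branches that use isoprenoids and lipids moved in both directions in the parental response. Ubiquinone and haem A synthesis genes rose in 6 of 12 cases (6 adjusted over the list alone; list adjusted p = 0.0611), with COQ4 at 1.39 ± 0.14. Dolichol and prenylation genes were higher in 5 and lower in 6 of 18 cases (5 and 6 adjusted over the list alone; list adjusted p = 0.654), with ALG13 at 1.74 ± 0.21 and SEC59 at -0.97 ± 0.13. RER2, of dolichol synthesis, was higher in the mutant in glucose by 0.64 ± 0.14. Sterol regulator, uptake and hypoxic cell wall genes were higher in 4 and lower in 7 of 20 cases (4 and 7 adjusted over the list alone; list adjusted p = 0.43), with ROX1 at 1.52 ± 0.15 and YEH1 at -1.23 ± 0.11. Fatty acid and phospholipid synthesis genes were higher in 6 and lower in 7 of 18 cases (6 and 7 adjusted over the list alone; list adjusted p = 0.858), with CHO1 at 1.54 ± 0.17. Unfolded protein response genes were higher in 4 and lower in 5 of 14 cases (4 and 5 adjusted over the list alone; list adjusted p = 0.671), with MPD1 at 1.05 ± 0.17 and ERO1 at -0.99 ± 0.18. Histone and DNA replication genes rose in 4 of 15 cases and fell in 1 (4 and 1 adjusted over the list alone; list adjusted p = 0.603), with RFA1 at 1.496 ± 0.11. RNR1 had a larger ratio in the mutant response by 1.18 ± 0.19.

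Of the mating type lists, a-mating type and pheromone response genes were higher in 2 and lower in 2 of 9 cases in the parental response (2 and 2 adjusted over the list alone; list adjusted p = 0.879), with FUS3 at 1.81 ± 0.10. Of 4 measured alpha-mating type and sporulation genes, too few for a list test, 1 was higher in mutant glycerol cells, IME1 at 1.22 ± 0.19 (2 adjusted over the list alone). ERG12 chromosome neighbours were higher in 3 and lower in 3 of 6 cases in the parental response (3 and 3 adjusted over the list alone; list adjusted p = 0.923). In the mutant 1 of 6 was lower in glucose (1 adjusted over the list alone; list adjusted p = 0.902). Strain marker genes passed in glucose for URA3 alone, 1 of 5 (1 adjusted over the list alone; list adjusted p = 0.0186, and adjusted p = 0.594 with an estimated correlation).

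MET17 is deleted in the usual BY4741 genotype, yet its probe was well above background in both strains. Background as the only source of this signal was excluded, since MET17 was above background on 16 of 16 channels, and its ratio followed the mean of the sulfate list over 8 arrays at r = 0.985. HIS3 and LEU2 were above background on 0 of 16 channels each. Diploid cells were weighed through genes specific to a mating type. Of 10 such genes, STE6 and SAG1 were above background on all 16 channels, 1 of 6 a-specific and 1 of 4 alpha-specific genes. The other 8 were above background on fewer channels or on none. MFA1 was above on 13, AGA2 on 8, STE2 on 6 and MFA2 on 2. STE3 was above on 4, MF(ALPHA)1 on 3, and BAR1 and MF(ALPHA)2 on 0. The highest processed signals were 135 for MFA1 and 53.2 for MF(ALPHA)1, against 3350 for STE6 and 959 for SAG1. This leaves the question of ploidy open. The genotype at MET17 was not analysed here.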
